A study of Homo sapiens with 8 samples.

How the data were processed

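Expression was measured on Illumina arrays of biotin-labelled cRNA from HaCaT keratinocytes, in 4 groups of 2 arrays: Cas9 control and REDD1 KO cells, each with vehicle (0.1% acetone) or 1 µM fluocinolone acetonide for 24 h. Groups, treatment and experiment number were taken from the labels, which give an experiment number and a matching batch. The authors deposited a non-normalized table of probe intensity on a linear scale, with a detection p-value per probe and array. The deposited value table holds log2 signal that was background-corrected and quantile-normalized. Per the submitters' processing notes limma was used, with a version not given in the sources used here. The deposited log2 values differed little from limma's neqc of the intensities, and they served as an alternative. The number of arrays limits the precision of every value.

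Intensities of 48099 probes were background-corrected by limma's normal-exponential model with detection p-values in place of control labels and an offset of 16. The 784 probes absent from the value table, whose kind is not given in the sources used here, were then dropped, and 47315 probes were quantile-normalized and put on the log2 scale. Detection p-values moved in steps of 1/770. Probes with a detection p of 0.05 or lower on at least 2 of 8 arrays were kept, which left 23476. Of the probes, 30110 had 1 symbol in the reference, 8 had several and 17197 had none listed. For 30071 probes a current symbol was found by Entrez identifier, whether or not it differed from the listed one. A gene with several probes was represented by the one with the highest mean, and unnamed probes were tested on their own. This gave 18979 features, 12846 named genes and 6133 unnamed probes. The reference gene order (GRCh38.p14) was used for names and neighbours alone, and no positions are reported.

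Computation used R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and figures used numpy 2.4.6 and matplotlib 3.10.9. A linear model with a mean per group and the experiment as a block was fitted by limma with empirical Bayes moderation (3 residual and 5.964 prior degrees of freedom). The contrasts were FA against vehicle in each genotype, REDD1 KO against Cas9 control under each treatment, the difference of the FA responses, and the averages over genotype and over treatment. Calls were made at a Benjamini-Hochberg adjusted p of 0.05 within each contrast, by two-sided tests. Errors are the standard error of the moderated fit (SE) or the standard deviation of 2 arrays (SD). The pairing of groups by experiment was checked once: after removing group means, deviations from the group correlated within an experiment with r of 0.485 to 0.628 over 6 pairs.

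The groups of genes were 28 lists of pathways, complexes and markers of other cell types, with at least 5 measured members. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, where fry tests whether the members of a list move and does not compare them with other genes. Benjamini-Hochberg adjustment covered the lists of a contrast. Counts adjusted over the list alone used the p-values of its measured members. Of 48 list calls over the 5 contrasts of single comparisons and difference, 1 held with an estimated correlation. Named genes were, per contrast, the 10 with the largest positive and the 10 with the largest negative change among eligible called genes. These had an official symbol, changed the same way in both experiments and were detected on both arrays of the brighter group. The difference of responses has no brighter group. There, a more positive difference needed detection on both arrays of Cas9 control vehicle and of REDD1 KO FA. A more negative one needed it in Cas9 control FA and REDD1 KO vehicle. Up to 4 members of a described list, those with the lowest p, and DDIT4 were named as well. Genes named beyond this rule were chosen after their values were seen.

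The groups, contrasts, gene lists, named-gene rule and alternatives were fixed before the data were examined. Alternatives were no background correction, median scaling, quantile normalization within each experiment, the deposited values, no detection filter, probes with a detection p of 0.01 on all 8 arrays, every probe tested, the mean of a gene's probes, no experiment block, experiment as a random block, 4 arrays alone, trend and robust moderation, array weights, each array left out and each experiment alone. The method was tested on simulated data with changes of known size, put into 50 features per size in Cas9 control cells with FA. The simulation used independent normal noise with each feature's moderated spread and a common baseline for all groups. Its recovery rates hold for that setting and may differ from those in the data. For FA in Cas9 control cells it recovered 58% of changes of 0.5, 98% of 1 and 100% of 1.5 and 2 on the log2 scale, with 15 calls among unchanged features. For the difference of responses it recovered 12%, 88%, 100% and 100%, with 10 such calls. No array was left out of the main analysis.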

Results

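Gene expression was measured on 8 Illumina arrays of HaCaT cells, an immortalised human keratinocyte line. The arrays form a design of 2 genotypes by 2 treatments. REDD1 KO cells carried a knockout of REDD1, the protein of the gene DDIT4 and a stress-induced inhibitor of the growth kinase complex mTORC1, and Cas9 control cells served as their control. Cells received fluocinolone acetonide (FA), a synthetic glucocorticoid used on skin, at 1 µM for 24 h, or vehicle (0.1% acetone). Each of the 4 groups had 2 arrays, one in each of 2 experiments, so n = 2 in every group and both experiments held all groups. Between 40.87% and 42.9% of probes were detected per array, and 18979 features entered the tests, of which 12846 were named genes. Every test used limma with the experiment as a block. The p-values rest on how the groups varied between 2 experiments on the same lines, after the shift shared by all groups was removed.

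Arrays of the same group had a correlation across genes of 0.9904 to 0.9915 between experiments, and arrays of different genotype 0.9509 to 0.9679. The main component of the variance took 70.4% and separated the genotypes. The next component took 12.9% and separated the experiments, and the component after it took 6.64% and separated the treatments.

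DDIT4 was lower in REDD1 KO cells than in Cas9 control cells and rose with FA in both. Its probe (ILMN_1661599) read log2 11.37 ± 0.00887 (SD, n = 2) in Cas9 control cells with vehicle and 12.18 ± 0.073 (SD, n = 2) with FA. In REDD1 KO cells it read 9.07 ± 0.112 (SD, n = 2) with vehicle and 10.33 ± 0.03 (SD, n = 2) with FA. The KO difference was -2.30 on the log2 scale with vehicle (adjusted p = 1.36e-06) and -1.86 with FA (adjusted p = 3.13e-06). FA raised the DDIT4 signal by 0.81 ± 0.106 (SE) in Cas9 control cells (adjusted p = 0.00489) and by 1.25 ± 0.106 (SE) in REDD1 KO cells (adjusted p = 0.000977). The difference between these responses was 0.44 ± 0.15 (SE) and did not pass the test (adjusted p = 0.353). The DDIT4 call for FA in Cas9 control cells was lost without vehicle array 1 (adjusted p = 0.0602), vehicle array 2 (0.063) or FA array 2 (0.0742) of those cells. The probe was detected on all 4 REDD1 KO arrays, and the sources do not place it relative to the edit, so its signal does not check the knockout. The arrays measure transcript and not protein.

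**Figure D1:**
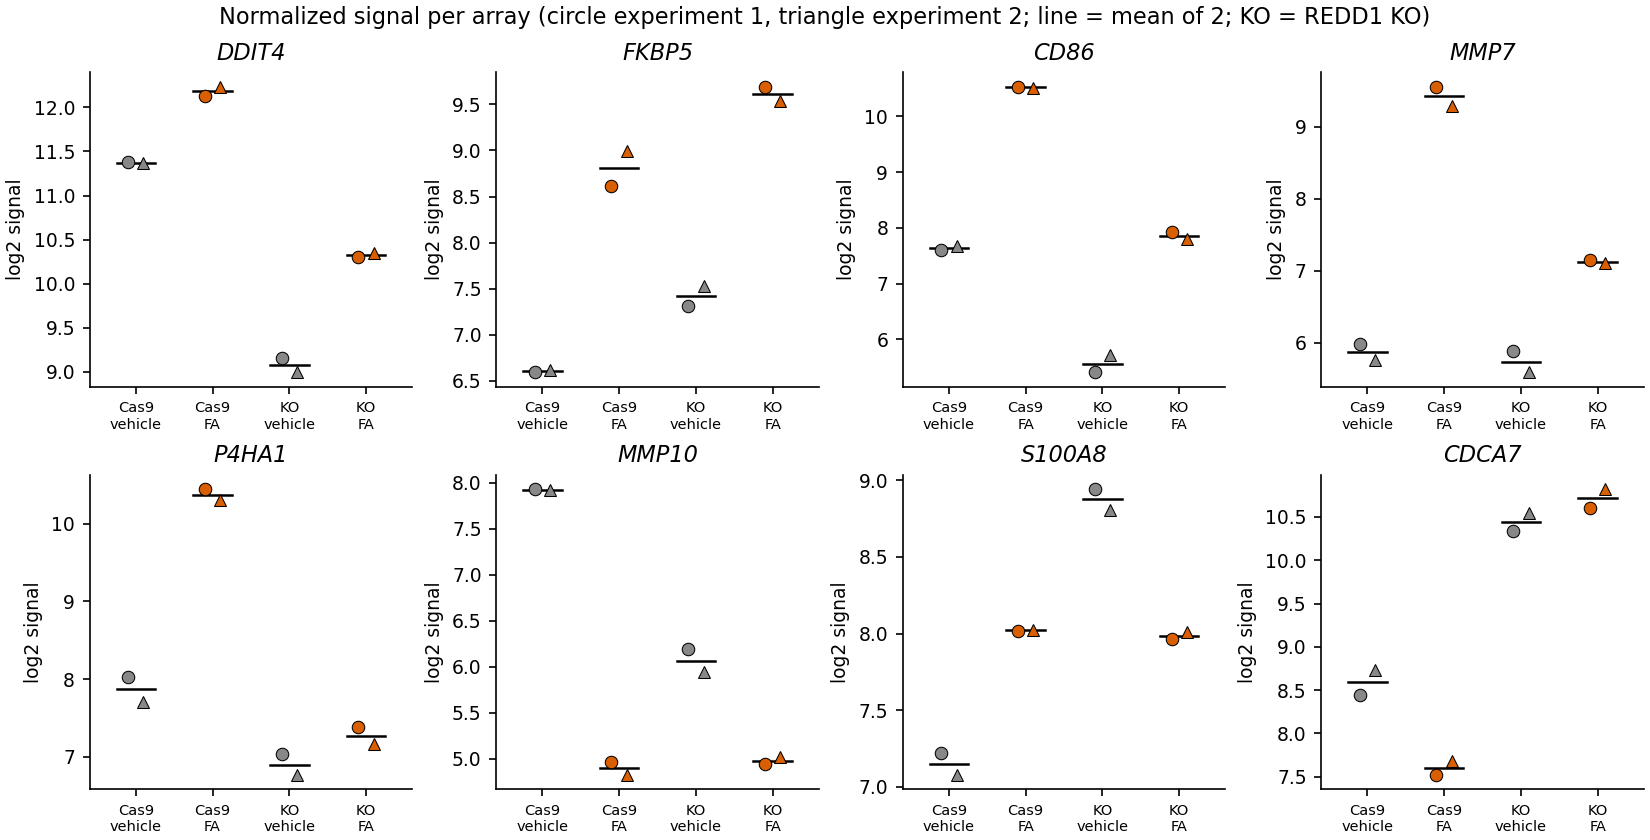
Log2 signal (y axis) of selected genes in the 4 groups (x axis, KO is REDD1 KO), with each point an array and each line the mean of 2 arrays. DDIT4 lies at 11.37 and 12.18 in Cas9 control cells with vehicle and FA, and at 9.07 and 10.33 in REDD1 KO cells.

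The response of control keratinocytes to the glucocorticoid was asked by comparing FA with vehicle in Cas9 control cells. MMP7, a matrix metalloproteinase of epithelia, rose by 3.56 ± 0.107 on the log2 scale (SE, n = 2 per group, adjusted p = 1.02e-06). HSD17B2, which inactivates estradiol and testosterone, was at least 10.9-fold higher, its vehicle signal being under background. CD86, a co-stimulatory ligand of T cells, rose by 2.88 ± 0.123, the acute-phase protein gene SAA1 by 2.47 ± 0.102, and P4HA1, a prolyl hydroxylase of collagen, by 2.51 ± 0.1. The glucocorticoid-induced genes FKBP5 and KLF9 rose by 2.20 ± 0.135 and 2.30 ± 0.213. MMP10, the stromelysin 2 gene, fell by 3.03 ± 0.112 and MMP1, the interstitial collagenase gene, by 1.53 ± 0.181. The suprabasal keratin KRT1 fell by 1.41 ± 0.104 and the monocyte chemokine CCL2 by 1.40 ± 0.107.

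In all, 421 features changed with FA in Cas9 control cells, 207 higher and 214 lower, and 352 of them were named genes. The rule also named PNLIPRP3, a pancreatic lipase relative (2.56), PHACTR3 (at least 4.34-fold) and TFCP2L1 (at least 3.45-fold) on the higher side, and TNFRSF11B, the decoy receptor osteoprotegerin (at least 2.92-fold), ATP10B (-1.67), the protease gene ADAMTS1 (-1.63), CALB2 (-1.63, passing on 1 of its 2 probes), MAL (-1.40) and the keratin KRT3 (-1.36) on the lower side. A bound of this kind sets the dim group at the lowest signal that was detected on each of its arrays. Without the block on experiment the count was 123 (78 higher and 45 lower), and MMP1 lost its call (adjusted p = 0.0818). The balance of higher and lower depended on the processing, with 355 and 505 for probes detected on all 8 arrays and 498 and 663 with trend and robust moderation. The count was 120 without Cas9 control vehicle array 1 (80 higher and 40 lower), 155 without FA array 1, 123 without vehicle array 2 and 130 without FA array 2, where the lone array left in a group was assumed to vary like the other groups.

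DNA replication genes fell together with FA in Cas9 control cells. Of 28 measured members of that list, 13 fell and none rose, and 22 fell when adjusted over the list alone. The replicative helicase factors GINS2 and CDC45 fell by 1.08 and 0.95 on the log2 scale. The mean over the list was -0.51, and it was the list whose call held with an estimated correlation (camera adjusted p = 7.37e-20, adjusted p = 0.049 with an estimated correlation). Mitotic genes were lower as a list (camera adjusted p = 5.47e-09, adjusted p = 0.0562 with an estimated correlation), though of 30 members AURKB alone passed over all genes and 7 when adjusted over the list alone. AURKB, a kinase of chromosome segregation, fell by 0.52 and lost its call without any 1 of the 4 Cas9 control arrays or of the 2 REDD1 KO vehicle arrays (adjusted p = 0.0741 to 0.345) and without the block (0.527).

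Known glucocorticoid-induced genes rose with FA in Cas9 control cells, 12 of 28 rising and 1 falling, with 16 and 1 when adjusted over the list alone. TFCP2L1, FKBP5, the sodium channel subunit SCNN1A (1.49) and the transcription factor CEBPD (1.47) had the lowest p-values in the list (camera adjusted p = 1.17e-14, adjusted p = 0.123 with an estimated correlation). Metallothioneins, small metal-binding proteins, rose in 6 of 6 members, and in 6 when adjusted over the list alone, with MT1G at 1.25 and MT1E at 1.04 (camera adjusted p = 2.94e-12, adjusted p = 0.0562 with an estimated correlation). MT1G lost its call without the block (adjusted p = 0.104), and array probes of this family can cross-hybridise.

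Matrix and TGF-beta genes were lower with FA in Cas9 control cells, with 5 of 27 members falling and 10 when adjusted over the list alone. HAS3, a hyaluronan synthase, fell by 1.03 and TAGLN, an actin-binding protein, by 0.79 (camera adjusted p = 1.33e-06, adjusted p = 0.109 with an estimated correlation). TAGLN lost its call without FA array 1 (0.0753) or vehicle array 2 (0.0895) of those cells. Cholesterol synthesis genes were lower too, with 3 of 25 falling and 8 when adjusted over the list alone (camera adjusted p = 6.58e-05, adjusted p = 0.146 with an estimated correlation). HMGCS1, an early enzyme of the mevalonate pathway, fell by 0.90, a call lost without Cas9 control vehicle array 1 (0.0565). Inflammatory genes went both ways, with 6 of 33 rising and 7 falling, 8 and 10 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.415). MMP10, CCL2 and SAA1 are among them, as is the prostaglandin synthase PTGS2, which rose by 1.56.

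The same treatment in REDD1 KO cells gave the response of the knockout line. CD86 rose by 2.29 ± 0.123 on the log2 scale (SE, n = 2 per group, adjusted p = 8.02e-05), FKBP5 by 2.19 ± 0.135 and SCNN1A by 2.10 ± 0.111. The Wnt antagonist SFRP1 rose by 2.05 ± 0.11 and ANGPTL4, an inhibitor of lipoprotein lipase, by 1.83 ± 0.1, the latter passing on 1 of its 3 probes. The annexin ANXA10 fell by 1.71 ± 0.113, FLG, the barrier protein filaggrin, by 1.29 ± 0.126, and the neutrophil chemokine CXCL8 by 1.04 ± 0.103. MMP10 fell by 1.09 ± 0.112.

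In REDD1 KO cells 185 features changed with FA, 95 higher and 90 lower, and 157 were named genes. The rule also named PNLIPRP3 (1.99, vehicle signal measured on 1 of 2 arrays), FLRT3 (1.86), PHACTR3 (1.70), the adrenergic receptor ADRA1B (1.70) and ASAP3 (1.68) as higher. It named TMEM200A (-1.22), the long non-coding RNA MANCR (-1.17), ANKRD22 (-1.14), the adhesion protein CEACAM6 (-1.13), the anthrax toxin receptor ANTXR2 (-1.11) and the cornified envelope precursor SPRR3 (-1.04) as lower. Without the block on experiment the count was 43 (30 higher and 13 lower), and CXCL8 (adjusted p = 0.0634), CEACAM6 (0.117) and TMEM200A (0.106) lost their calls. It was 63 without REDD1 KO vehicle array 1, 42 without FA array 1, 60 without vehicle array 2 and 39 without FA array 2. Without REDD1 KO FA array 1 the calls of MMP10 (0.0569), SPRR3 (0.0569) and TMEM200A (0.122) were lost, without FA array 2 those of SPRR3 (0.0754) and TMEM200A (0.105), and without vehicle array 2 that of TMEM200A (0.0541).

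Glucocorticoid-induced genes rose with FA in REDD1 KO cells as well, 9 of 28 rising and none falling, or 14 and 3 when adjusted over the list alone. SCNN1A, ANGPTL4, FKBP5 and the leucine zipper protein TSC22D3 (1.67) had the lowest p-values in the list (camera adjusted p = 9.75e-09, adjusted p = 0.217 with an estimated correlation). Metallothioneins rose in 5 of 6 members and in 6 when adjusted over the list alone, MT1G by 1.00 (camera adjusted p = 4.05e-13, adjusted p = 0.119 with an estimated correlation), a call of MT1G lost without the block (adjusted p = 0.367). Inflammatory genes were lower as a list, with 6 of 33 falling and 2 rising, or 14 and 4 when adjusted over the list alone (camera adjusted p = 6.2e-06, adjusted p = 0.217 with an estimated correlation). CXCL8 and MMP10 fell while SAA1 rose by 1.33 and PTGS2 by 1.10, and PTGS2 lost its call without REDD1 KO FA array 2 (0.0624). Immediate-early genes were lower as a list, with 2 of 25 falling, PHLDA1 and IER3 (-0.92 and -0.81), or 9 falling and 2 rising when adjusted over the list alone (camera adjusted p = 0.000372, adjusted p = 0.217 with an estimated correlation). PHLDA1 lost its call without REDD1 KO vehicle array 1 (0.0595), vehicle array 2 (0.0666), FA array 2 (0.076) or the block (0.464). IER3 lost its call without FA array 1 (0.0837), vehicle array 2 (0.101), FA array 2 (0.0953) or the block (0.0557). Of the 28 DNA replication genes none passed with FA in REDD1 KO cells by limma, over all genes or when adjusted over the list alone, and the list mean was 0.016 (camera adjusted p = 0.683).

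**Figure D2:**
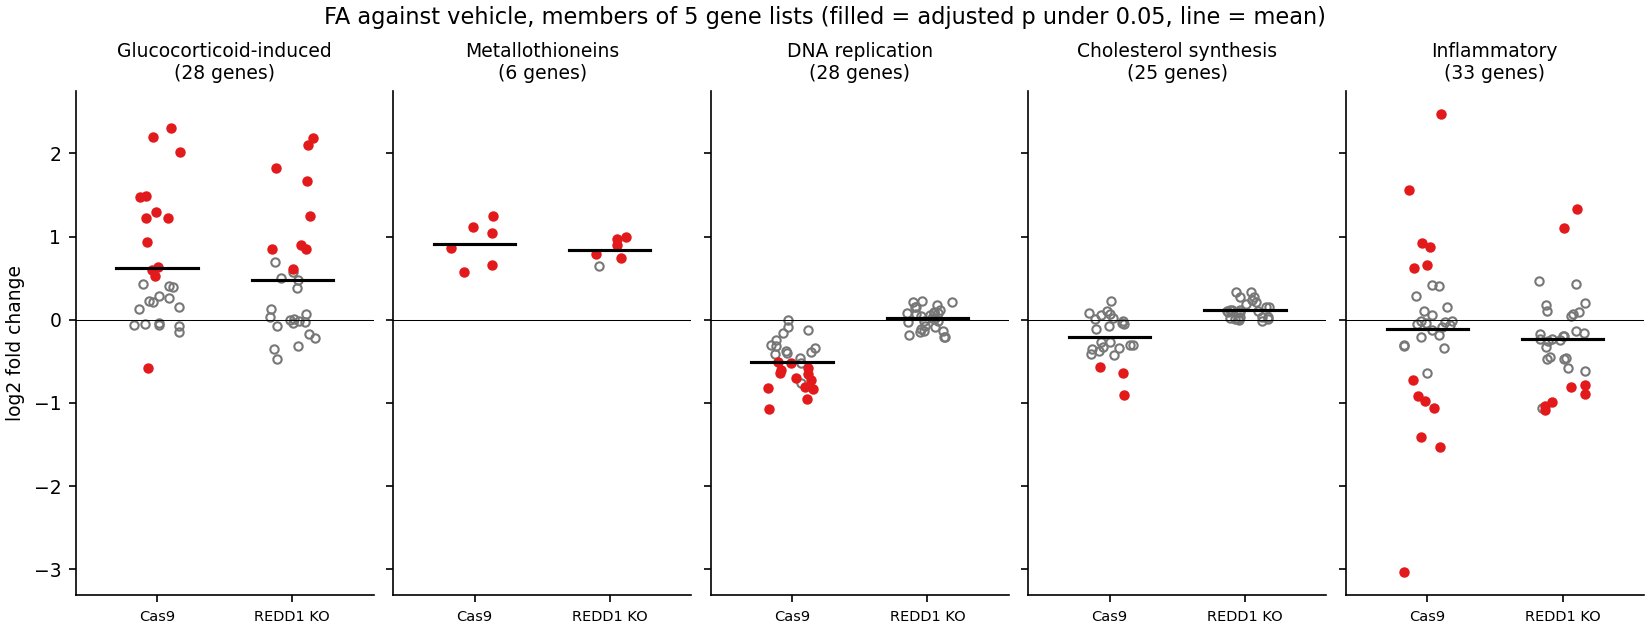
Log2 fold change with FA (y axis) of the members of 5 gene lists (panels) in Cas9 control and REDD1 KO cells (x axis), with each point a gene, filled where it passed the test, and each line the list's mean. The mean of the DNA replication list lies at -0.51 in Cas9 control cells and 0.016 in REDD1 KO cells.

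The comparison of the 2 responses asked whether the effect of FA differed between REDD1 KO and Cas9 control cells. Of the features higher with FA, 71 were shared by the 207 of Cas9 control cells and the 95 of REDD1 KO cells, where 1.04 would be shared if the calls were independent. Of the lower features 36 were shared, where 1.01 would be, and 2 features, the calprotectin subunit genes S100A8 and S100A9, were called in opposite directions. The calls of the 2 genotypes rest on the same spread estimate per feature, which can raise the overlap, so independence is a low baseline. CD86, FKBP5, PNLIPRP3, PHACTR3 and MMP10 were among the genes named in both. Across all genes, which are not independent replicates, the responses had r = 0.314 and a slope of 0.269. Between arrays of different experiments r was 0.24 and 0.209, and within experiments 0.201 and 0.237. The response of one genotype had r = 0.525 between the experiments in Cas9 control cells and 0.306 in REDD1 KO cells. The slopes between these repeats were 0.554 and 0.295, so the slope of 0.269 does not measure the relative size of the responses. Over the 561 features called for FA across both genotypes, the median response in the direction of the call was 0.57 in Cas9 control and 0.473 in REDD1 KO cells.

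MMP7, P4HA1 and HSD17B2 responded less to FA in REDD1 KO cells by the test of the difference (interaction). MMP7 read log2 5.87 with vehicle and 9.42 with FA in Cas9 control cells, and 5.73 and 7.12 in REDD1 KO cells, a difference of -2.17 ± 0.151 (SE, n = 2 per group, adjusted p = 0.00101). P4HA1 read 7.87 and 10.38 in Cas9 control cells and 6.90 and 7.27 in REDD1 KO cells, a difference of -2.14 ± 0.142 (adjusted p = 0.00101). For HSD17B2 the difference was -2.02 ± 0.144 (adjusted p = 0.00101), with Cas9 control cells under background in vehicle, so that the fitted value is no bound. HSD17B2 read 4.425 with vehicle and 7.954 with FA in Cas9 control cells, and 7.405 and 8.914 in REDD1 KO cells. Its level in REDD1 KO cells was thus the higher one under both treatments. S100A8 and S100A9 were higher with FA than with vehicle in Cas9 control cells and lower in REDD1 KO cells. The differences were -1.76 ± 0.147 (adjusted p = 0.00223) and -1.70 ± 0.149 (adjusted p = 0.00298). S100A8 read 7.151 with vehicle and 8.021 with FA in Cas9 control cells, and 8.875 and 7.985 in REDD1 KO cells. S100A9 read 7.59 and 8.509, and 9.539 and 8.757, in the same order. For both genes the genotypes lay further apart with vehicle than with FA. MMP10 fell less in REDD1 KO cells, by a difference of 1.95 ± 0.158 (adjusted p = 0.00205). It read 7.93 with vehicle and 4.89 with FA in Cas9 control cells, and 6.07 and 4.98 in REDD1 KO cells. Both FA levels lie near the lowest detected signal (4.50 to 4.54), and the vehicle level of REDD1 KO cells was the lower one.

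Altogether 40 features had responses that differed, 14 with a more positive and 26 with a more negative response in REDD1 KO cells, and 36 were named genes. That balance depended on the processing, with 189 and 155 without background correction, 184 and 127 with trend and robust moderation, and 47 and 49 for probes detected on all 8 arrays. Of the 36 named genes 14 were more positive and 22 more negative, and 7 and 14 of them were eligible under the naming rule. The largest called difference, 2.919 in size, belonged to a feature that the rule did not name. The calls of MMP7, P4HA1, HSD17B2, S100A8 and MMP10 were kept without each array and without the block. S100A9 lost its call without REDD1 KO FA array 1 (adjusted p = 0.0505) and without the block (0.113). More positive were also CDCA7 (1.26), KRT3 (1.24), ANGPTL4 (1.19, on 1 of 3 probes), GINS2 (1.16), the endothelial transcription factor SOX18 (1.05) and the cell cycle factor E2F2 (0.96). The SOX18 level of REDD1 KO cells with vehicle, 4.537, lay near the lowest detected signal. More negative were also the T cell inhibitory ligand VTCN1 (-1.29, under background in REDD1 KO cells with FA), SPRR1A (-1.29), the transglutaminase TGM2 (-1.26), TFCP2L1 (-1.17, under background in Cas9 control cells with vehicle) and SAA1 (-1.14, on 1 of 3 probes). As for HSD17B2, the fitted values of VTCN1 and TFCP2L1 are no bounds. VTCN1 read 4.576 in REDD1 KO cells with vehicle, also near the lowest detected signal, so a fall there could hardly be measured. Each of KRT3, ANGPTL4, GINS2, SOX18, E2F2, SPRR1A, TFCP2L1 and SAA1 lost its call without any 1 of the 8 arrays, and CDCA7, VTCN1 and TGM2 without any but Cas9 control vehicle array 1, with adjusted p from 0.0519 to 0.266. The count of 40 was 6 without the block on experiment. In Cas9 control cells it was 19 without vehicle array 1, 13 without FA array 1, 13 without vehicle array 2 and 15 without FA array 2, and in REDD1 KO cells 12, 8, 16 and 11 in the same order.

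**Figure D3:**
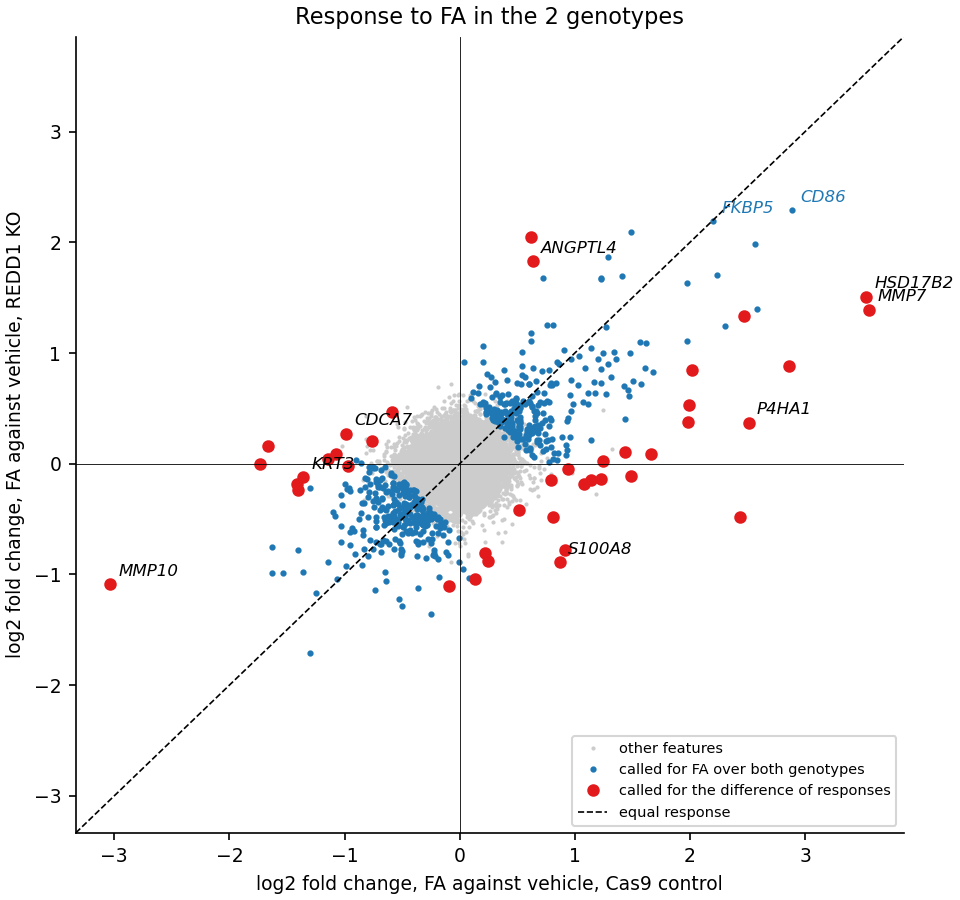
Log2 change with FA in REDD1 KO cells (y axis) against that in Cas9 control cells (x axis), each point a feature, with those of different response marked. Over 18979 features r was 0.314, and 40 features differed by the interaction test.

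Among gene lists, the DNA replication list differed in response, with a mean of 0.53 (camera adjusted p = 3.89e-17, adjusted p = 0.0609 with an estimated correlation). Of its 28 members GINS2 passed over all genes, and 19 when adjusted over the list alone. CDC45 and MCM6 had differences of 0.92 (adjusted p = 0.0603) and 0.96 (adjusted p = 0.0645). Cholesterol synthesis genes had a mean difference of 0.33, with 0 of 25 passing by limma over all genes and 8 when adjusted over the list alone (camera adjusted p = 2.39e-08, adjusted p = 0.154 with an estimated correlation). HMGCS1 differed by 0.94 (adjusted p = 0.0716) and FDPS, which makes farnesyl diphosphate, by 0.75 (adjusted p = 0.116). The mitotic list had a mean difference of 0.19 (camera adjusted p = 0.000166, adjusted p = 0.154 with an estimated correlation) and the matrix list 0.19 (camera adjusted p = 0.00834, adjusted p = 0.294 with an estimated correlation), with 0 members of either passing by limma over all genes. When adjusted over the list alone 0 of 30 mitotic genes passed, and of 27 matrix genes 4 had a more positive and 1 a more negative response.

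The difference between the lines without FA was asked by comparing REDD1 KO with Cas9 control cells under vehicle. The elastase inhibitor PI3 was higher in REDD1 KO cells by 4.71 ± 0.117 on the log2 scale (SE, n = 2 per group, adjusted p = 7.47e-08). The interleukin 1 genes IL1B and IL1A were higher by 3.51 ± 0.123 and 3.46 ± 0.111, and the gelatinase MMP9 was at least 9.03-fold higher. LGALS7B and LGALS7, which encode galectin 7 of stratified epithelia, were lower, at -5.75 ± 0.122 and -5.46 ± 0.113, and as near copies their probes can cross-hybridise. CCL2 was at -4.66 ± 0.107, with REDD1 KO cells measured on 1 of 2 arrays, and the tight junction gene CLDN8 at -4.04 ± 0.109.

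With vehicle 7396 features differed, 39% of those tested, with 3730 higher and 3666 lower in REDD1 KO cells, and 5851 were named genes. With median scaling 4315 were higher and 3243 lower. The rule named as higher also the calcium-binding CALB2 (3.32, on 1 of 2 probes), BASP1 (3.17), COXFA4L3 (3.01), HSD17B2 (at least 7.43-fold) and the transcription factors ETV5 (2.88) and ZIC2 (2.84). It named as lower also TCEA3 (-4.22), MPPED2 (at least 15.5-fold), TUSC3 (at least 14-fold), AGR2 (-3.69), the collagenase MMP13 (-3.68, REDD1 KO measured on 1 of 2 arrays) and OLFM4 (-3.62). Without the block on experiment the count was 4796, and all 20 genes named by the rule kept their calls there and without each array. The labels name no separate clones within a genotype, so the difference holds for these lines.

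DNA replication and ribosome biogenesis genes were higher in REDD1 KO cells under vehicle. Of 28 DNA replication genes 25 were higher, 26 when adjusted over the list alone, with GINS2 at 1.65 and CDC45 at 1.62 (camera adjusted p = 1.39e-10, adjusted p = 0.0877 with an estimated correlation). Of 22 ribosome biogenesis genes 18 were higher, and 18 when adjusted over the list alone, with the nucleolar proteins NOP16 at 1.90 and RRS1 at 1.88 (camera adjusted p = 5.34e-09, adjusted p = 0.0877 with an estimated correlation). Mitotic genes were higher in 12 of 30, also 12 when adjusted over the list alone, among them the centromere histone CENPA at 1.14 (camera adjusted p = 0.00159, adjusted p = 0.15 with an estimated correlation). Immediate-early and ERK pathway genes were higher in 16 of 25 and lower in 5, or 17 and 5 when adjusted over the list alone, with FOSL1 at 1.93 and ATF3 at -1.67 (camera adjusted p = 0.00118, adjusted p = 0.15 with an estimated correlation). Inflammatory genes were higher in 14 of 33 and lower in 5, with the same counts when adjusted over the list alone (camera adjusted p = 0.0133, adjusted p = 0.331 with an estimated correlation).

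Basal adhesion genes were lower in REDD1 KO cells under vehicle in 9 of 14 and higher in 1, or 10 and 1 when adjusted over the list alone. The basal keratin KRT15 was at -2.29 and the anchoring fibril collagen COL7A1 at -1.12 (camera adjusted p = 0.000819, adjusted p = 0.15 with an estimated correlation). Atrophy and FOXO genes were lower in 11 of 17 and higher in 1, or 11 and 2 when adjusted over the list alone. The ubiquitin ligase FBXO32 was at -2.09 and the repressor BCL6 at -1.84 (camera adjusted p = 0.00159, adjusted p = 0.332 with an estimated correlation). NRF2-driven genes were lower in 10 of 20 and higher in 2, or 11 and 2 when adjusted over the list alone, with the aldo-keto reductase AKR1B10 at -2.79 (REDD1 KO measured on 1 of 2 arrays) and PIR at -1.32 (camera adjusted p = 0.00323, adjusted p = 0.282 with an estimated correlation). Fatty acid genes were lower in 9 of 21 and higher in 2, with the same counts when adjusted over the list alone (camera adjusted p = 0.0486, adjusted p = 0.492 with an estimated correlation). That list call was lost without Cas9 control vehicle array 1 (0.0589), vehicle array 2 (0.08), REDD1 KO vehicle array 2 (0.0906) or the block (0.0687).

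Under FA the genotypes were compared in the same way, to see how the lines differed when treated with the glucocorticoid. CALB2 (on 1 of 2 probes) was higher in REDD1 KO cells by 3.97 ± 0.106 on the log2 scale (SE, n = 2 per group, adjusted p = 1.02e-07), BASP1 by 3.86 ± 0.115, PI3 by 3.73 ± 0.117, IL1B by 3.61 ± 0.123 and IL1A by 3.29 ± 0.111. LGALS7B and LGALS7 were at -5.88 ± 0.122 and -5.27 ± 0.113, the mucosal protein AGR2 at -4.54 ± 0.114 and CLDN8 at -4.40 ± 0.109. The antimicrobial peptide gene DEFB1 was at -3.52 ± 0.183. In all 7662 features differed, 40.4% of those tested, with 3875 higher and 3787 lower (4035 and 3461 with median scaling), and 6073 were named genes. CDCA7 (3.11), ETV5 (3.09), TFPI2 (at least 7.83-fold), MMP9 (at least 7.52-fold) and RFTN1 (at least 6.84-fold) were the other higher genes of the rule. GPR15LG (-3.97) and TUSC3 (-3.53), each measured on 1 of 2 REDD1 KO arrays, OLFM4 (-3.97), TCEA3 (-3.87) and MPPED2 (at least 11.2-fold) were the other lower genes. Across genes, the KO difference under FA and that under vehicle had r = 0.901.

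DNA replication genes were higher in REDD1 KO cells under FA in 27 of 28 members, also 27 when adjusted over the list alone, with GINS2 at 2.81 and CDC45 at 2.54 (camera adjusted p = 9.93e-16, adjusted p = 0.0692 with an estimated correlation). Ribosome biogenesis genes were higher in 20 of 22, and 20 when adjusted over the list alone, with NOP16 at 1.93 (camera adjusted p = 7.3e-09, adjusted p = 0.0871 with an estimated correlation). Mitotic genes were higher in 20 of 30, and 22 when adjusted over the list alone, with the apoptosis inhibitor BIRC5 at 1.48 (camera adjusted p = 1.28e-06, adjusted p = 0.0871 with an estimated correlation). Cholesterol synthesis genes were higher in 14 of 25 and lower in 2, or 16 and 2 when adjusted over the list alone, with HMGCS1 at 1.72 and FDPS at 1.24 (camera adjusted p = 0.000322, adjusted p = 0.221 with an estimated correlation). Immediate-early genes were higher in 14 and lower in 4 of 25, with the same counts when adjusted over the list alone (camera adjusted p = 0.00777, adjusted p = 0.221 with an estimated correlation).

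Lower lists under FA were the atrophy and FOXO genes, with 11 of 17 lower and 1 higher in REDD1 KO cells. These counts were 12 and 1 when adjusted over the list alone, FBXO32 being at -2.02 (camera adjusted p = 0.000608, adjusted p = 0.239 with an estimated correlation). Basal adhesion genes were lower in 8 of 14 and higher in 1, with the same counts when adjusted over the list alone, KRT15 being at -2.24 (camera adjusted p = 0.00932, adjusted p = 0.224 with an estimated correlation). NRF2-driven genes were lower in 7 of 20 and higher in 2, the same when adjusted over the list alone (camera adjusted p = 0.0356, adjusted p = 0.239 with an estimated correlation), a call lost without REDD1 KO FA array 2 (0.0658). Cornified envelope and suprabasal genes were lower in 13 of 29 and higher in 4, the same when adjusted over the list alone, with the envelope precursor IVL at -1.66 and CNFN at -1.57 (camera adjusted p = 0.0483, adjusted p = 0.239 with an estimated correlation). That call was lost without REDD1 KO FA array 2 (0.0756) and without the block (0.0519).

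**Figure D4:**
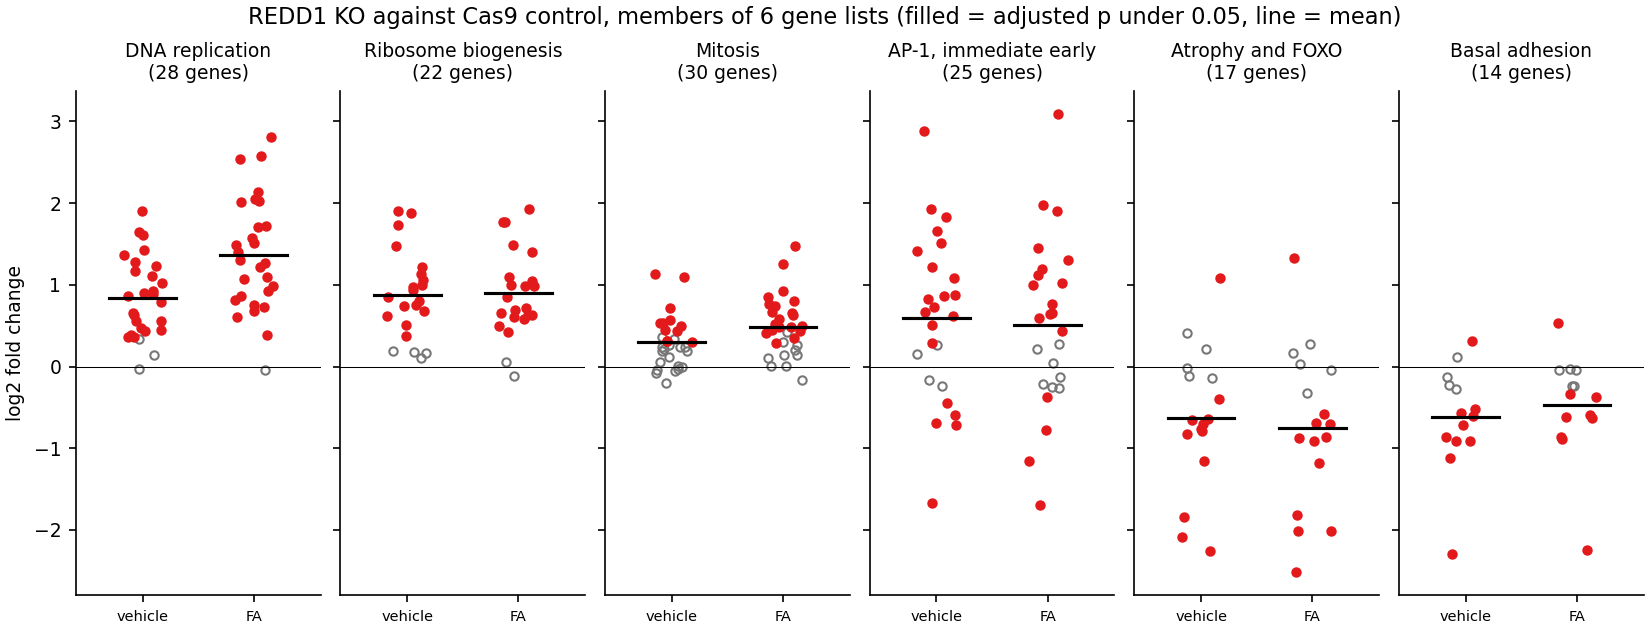
Log2 fold change of REDD1 KO against Cas9 control cells (y axis) of the members of 6 gene lists (panels) under vehicle and under FA (x axis), with each point a gene, filled where it passed the test, and each line the list's mean. The mean of the DNA replication list lies at 0.84 with vehicle and 1.36 with FA.

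Averaged over both genotypes, 561 features changed with FA, 273 higher and 288 lower, and 468 were named genes. Without the block on experiment the count was 209 (119 higher and 90 lower), and each of the 8 arrays moved it by more than 1.5 times. In Cas9 control cells it was 300 without vehicle array 1, 324 without FA array 1, 278 without vehicle array 2 and 282 without FA array 2, and in REDD1 KO cells 320, 308, 311 and 332 in the same order. Averaged over both treatments, 9505 features differed between the genotypes, 4748 higher and 4757 lower in REDD1 KO cells (5121 and 4321 with median scaling). GINS2 and HMGCS1 are examples of genes whose KO difference was larger with FA than with vehicle by value, and of these the difference of response passed for GINS2 alone.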

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

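Of the tests used here to weigh explanations, the test of a floor on the response of DNA replication genes was chosen only after the result was seen, as was the adjustment of the fry test over the set and its 2 directions. The results listed here concern the difference between REDD1 KO and Cas9 control cells in the response to FA. The single genes passed the interaction test, as 40 features did. The gene lists were those that camera called for this difference at the preset correlation. The set of features called for FA across both genotypes was tested by fry. Groups of 2 arrays were not tested for an outlying array within a group.

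Among named genes the difference of response (REDD1 KO minus Cas9 control, log2) was 1.95 for MMP10, 1.26 for CDCA7, 1.24 for KRT3, 1.19 for ANGPTL4, 1.16 for GINS2, 1.05 for SOX18 and 0.96 for E2F2. It was -2.17 for MMP7, -2.14 for P4HA1, -2.02 for HSD17B2, -1.76 for S100A8, -1.70 for S100A9, -1.29 for VTCN1, -1.29 for SPRR1A, -1.26 for TGM2, -1.17 for TFCP2L1 and -1.14 for SAA1. HSD17B2 and TFCP2L1 were under background in Cas9 control cells with vehicle and VTCN1 in REDD1 KO cells with FA, so their fitted values are no bounds. SOX18 and VTCN1 lay near the lowest detected signal in REDD1 KO cells with vehicle.

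Among gene lists the mean difference of response was 0.527 for DNA replication, 0.328 for cholesterol synthesis, 0.191 for mitosis, 0.187 for matrix and TGF-beta genes and 0.153 for basal adhesion. It was -0.277 for immune and endothelial markers, -0.164 for interferon genes, -0.145 for antigen presentation, -0.142 for glucocorticoid-induced genes and -0.13 for inflammatory genes. With an estimated correlation none of these 10 lists passed, the lowest being the adjusted p = 0.0609 with an estimated correlation of DNA replication. Basal adhesion lost its call without any 1 of the 8 arrays (adjusted p = 0.0676 to 0.141). Glucocorticoid-induced genes lost theirs without Cas9 control vehicle array 1 (0.124) or FA array 2 (0.226), or REDD1 KO vehicle array 1 (0.0906) or FA array 2 (0.335). Antigen presentation lost its call without Cas9 control vehicle array 1 (0.155), FA array 1 (0.116) or FA array 2 (0.0644), or REDD1 KO vehicle array 2 (0.229) or FA array 2 (0.335). Inflammatory genes lost theirs without any array but Cas9 control FA array 2, and immune and endothelial markers without any array but Cas9 control FA array 1 (adjusted p = 0.0559 to 0.218 and 0.0663 to 0.141). Without the block on experiment the calls of basal adhesion (0.0747), glucocorticoid-induced genes (0.0575), antigen presentation (0.0727) and inflammatory genes (0.0747) were lost.

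Over the 561 features called for FA across both genotypes, the response was smaller in REDD1 KO cells in 347 (61.9%), with a median signed difference of -0.1, and -0.11 and -0.112 within the experiments. Limma's fry gave adjusted p = 0.00452 for the whole set, and the median was -0.143 for features higher with FA (adjusted p = 0.00452) and -0.0581 for those lower (adjusted p = 0.00565). Compression of dim probes is argued against, since the 181 members brighter than log2 8 had a median of -0.134. Less room for a response from a changed vehicle level cannot be told apart from other causes, since the vehicle difference and the response difference correlated weakly across experiments and genes (r = -0.163 and -0.17). A smaller response of the set may therefore be biological or follow from vehicle levels, and the knockout as its source was not tested.

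DNA replication genes fell with FA in Cas9 control cells (mean -0.511 over 28 genes) and had a mean of 0.016 in REDD1 KO cells. No single array made the difference, whose mean was 0.495 to 0.559 without each array, with the camera call kept each time at the preset correlation (adjusted p = 0.0609 with an estimated correlation on all arrays). A floor on the response is argued against, since REDD1 KO cells had a vehicle level higher by 0.838 on average and so room to fall. A hypothesis is that REDD1 KO cells may keep replication genes expressed under FA; a difference between the lines other than the knockout stays open and was not tested.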

How the results depend on the processing

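Every alternative was planned before the data were examined. Signal over background limits dim genes, and 2 arrays per group limit the precision. Leaving out an array leaves a group with 1 array that is assumed to vary like the other groups. Without the replicate block, which pairs the groups by experiment, the counts were 123 for FA in Cas9 control cells, 43 for FA in REDD1 KO cells, 4796 for REDD1 KO with vehicle, 6 for the difference of responses and 209 for FA over both genotypes. Without background correction 1132, 526, 344 and 1264 features were called for FA in Cas9 control cells, in REDD1 KO cells, for the difference and for FA over both genotypes. With probes detected on all 8 arrays, and so fewer tested, these were 860, 339, 96 and 929, and with trend and robust moderation 1161, 581, 311 and 1284. For FA in Cas9 control cells, array weights gave 663 and the 4 arrays alone 243. The similarity of the responses (r across genes, 0.314) was 0.392 without background correction, 0.264 without a detection filter, 0.387 with probes detected on all arrays, and 0.201 and 0.237 in experiment 1 and 2 alone. Of 48 list calls 1 held with an estimated correlation, and fry, which asks another question, made 81. Apart from the fewer probes and arrays, the cause was not tested.

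With each array left out, counts ranged from 120 to 369 for FA in Cas9 control cells, 39 to 169 in REDD1 KO cells, 8 to 19 for the difference, 278 to 332 for FA over both genotypes, and the similarity from 0.245 to 0.3. The counts for REDD1 KO with FA and over both treatments, and the DDIT4 difference, stayed within bounds under all alternatives run, with DDIT4 between -2.40 and -2.20 over the arrays left out. No single gene or list result changed direction, but the balance within the counts moved. The share of higher features ran from 41.3% to 66.7% for FA in Cas9 control cells, 49.5% to 69.8% in REDD1 KO cells, 46.3% to 56.9% over both genotypes and 16.7% to 59.2% for the difference. It ran from 50% to 57.1% for REDD1 KO with vehicle, 50.1% to 53.8% with FA and 49.4% to 54.2% over both treatments. Of 376 results for single genes 275 kept their calls under each alternative that gave them a value, and of 48 list calls 1 did. Experiments alone give values without a test, and they, the 4 arrays alone and the probes detected on all 8 arrays give no value for some results. No scaling moved the median of all genes by more than 0.1.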

Other observations

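No test in this part was chosen only after its result was seen. Several gene groups outside the lists described so far held members that differed between REDD1 KO and Cas9 control cells under vehicle, in no uniform direction. Of all 12846 named genes 5851 differed in this comparison, so such member counts alone do not set a list apart from other genes. Regulators of mTOR signalling, the pathway REDD1 inhibits, were higher in 6 of 27 and lower in 6, or 8 and 7 when adjusted over the list alone (camera adjusted p = 0.973, mean -0.0957 and median 0.0914, which differ in sign). SESN3, a sestrin, was at -2.26 and TXNIP, a thioredoxin inhibitor, at -1.51. Autophagy and lysosome genes were lower in 11 of 28 and higher in 5, or 13 and 5 when adjusted over the list alone, with the cathepsin CTSB at -2.02 (camera adjusted p = 0.1). A list of simple epithelial, stress and other keratins had 5 of 7 members lower and 2 higher, the same when adjusted over the list alone. KRT4 was at -2.01 and KRT16 at -1.47 (camera adjusted p = 0.0782). Hypoxia genes were higher in 11 of 29 and lower in 11, or 12 and 11 when adjusted over the list alone, with the hexokinase HK2 at 2.32 and NDRG1 at -1.88 (camera adjusted p = 0.825). Notch and Wnt genes were lower in 9 of 21 and higher in 4, or 9 and 5 when adjusted over the list alone, with NOTCH1 at -1.64 (camera adjusted p = 0.243, mean -0.255 and median 0.0076).

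Targets of p53 were higher in 6 of 21 and lower in 6 with vehicle, or 7 and 9 when adjusted over the list alone, with the nuclease AEN at 2.33 and TP53INP1 at -2.54 (camera adjusted p = 0.929, median -0.0833 and mean 0.0204). ATF4 and amino acid genes were higher in 7 of 26 and lower in 8, or 10 and 9 when adjusted over the list alone, with STC2 at 1.98 and the serine synthesis enzyme PHGDH at -1.69 (camera adjusted p = 0.914). Interferon genes were higher in 8 of 31 and lower in 9, or 8 and 10 when adjusted over the list alone, with IRF7 at -1.27 (camera adjusted p = 0.901, median 0.126 and mean -0.0637). Unfolded protein genes were higher in 8 of 19 and lower in 2, the same when adjusted over the list alone, with DNAJC3 at 1.23 (camera adjusted p = 0.216). Respiratory chain genes were higher in 4 of 32 and lower in 2, or 3 and 1 when adjusted over the list alone, with UQCRQ at 0.64 (camera adjusted p = 0.532). Antigen presentation genes were higher in 1 of 15 and lower in 3, or 1 and 2 when adjusted over the list alone (camera adjusted p = 0.914, with mean 0.00622 and a test direction of down). Of the markers of other cell types, 1 of 6 melanocyte genes was lower and 0 higher by limma (camera adjusted p = 0.929, median 0.058 and mean -0.0585), 2 of 9 fibroblast genes were higher and 4 lower (0.702), and 1 of 5 immune and endothelial genes was higher and 2 lower (0.702, median 0.0489 and mean -0.225). These counts were the same when adjusted over each list alone. Among the fibroblast genes the proteoglycan genes DCN and LUM were at least 2.84-fold and 1.9-fold lower, and MFAP5 was at 2.25.

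With FA in Cas9 control cells fibroblast markers were not called by camera (adjusted p = 0.302), with a median of 0.0968 and a mean of -0.167. Of 9 members 2 fell, also 2 when adjusted over the list alone, DCN by 0.97 and LUM at least 1.89-fold. Fry, which asks another question, gave adjusted p = 0.0232 for a lower list. Cornified genes had a mean of -0.0147 and a test direction of up (camera adjusted p = 0.835). Called as higher were antigen presentation (camera adjusted p = 0.0085, adjusted p = 0.262 with an estimated correlation), atrophy and FOXO genes (0.0144, adjusted p = 0.359 with an estimated correlation) and interferon genes (0.0421, adjusted p = 0.262 with an estimated correlation). Notch and Wnt genes were called as lower (0.0291, adjusted p = 0.261 with an estimated correlation). In this order 0, 1, 0 and 3 members passed by limma over all genes, and 1, 1, 0 and 5 when adjusted over the list alone. The atrophy and FOXO member that passed was KLF9, which is also on the glucocorticoid-induced list. Among the Notch and Wnt genes HEY1 (-1.15), SFRP1 (at least 1.35-fold higher) and WNT4 (-0.64) passed. SFRP1 and WNT4 lost their calls without any 1 of the 4 Cas9 control arrays (0.0778 to 0.244 and 0.107 to 0.212), and HEY1 without the block (0.0737). Atrophy and FOXO genes lost their call without Cas9 control vehicle array 1. Notch and Wnt genes lost theirs without that array or FA array 1, and antigen presentation without either of those arrays. Interferon genes lost theirs without any of the 4 Cas9 control arrays or either REDD1 KO FA array.

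With FA in REDD1 KO cells 3 more lists were called by camera as higher, cholesterol synthesis (camera adjusted p = 0.00617, adjusted p = 0.217 with an estimated correlation), basal adhesion (0.0283, adjusted p = 0.217 with an estimated correlation) and fatty acid genes (0.0303, adjusted p = 0.477 with an estimated correlation). By limma 0 of 25, 1 of 14 and 3 of 21 of their members rose and 0 fell, or 0, 2 and 3 rose and 0 fell when adjusted over each list alone. Called as lower were immune and endothelial markers (0.0182, adjusted p = 0.217 with an estimated correlation), Notch and Wnt genes (0.0254, adjusted p = 0.217 with an estimated correlation) and cornified genes (0.0404, adjusted p = 0.217 with an estimated correlation). By limma 0 of 5, 1 of 21 and 3 of 29 of their members fell and 0, 1 and 2 rose, or 0, 6 and 9 fell and 0, 1 and 3 rose when adjusted over each list alone. Each of the 6 lists lost its call without at least 1 REDD1 KO array: cholesterol synthesis without vehicle array 1 (0.156), fatty acid genes without FA array 1 (0.279) or vehicle array 2 (0.136), cornified genes without FA array 1 (0.0539), vehicle array 2 (0.252) or FA array 2 (0.178), Notch and Wnt genes without vehicle array 1 (0.0901), FA array 1 (0.109) or vehicle array 2 (0.055), and basal adhesion and the immune and endothelial markers without any of the 4 (0.055 to 0.109 and 0.0504 to 0.0839).

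The breadth of the KO difference was weighed against technical explanations. Of 12824 genes with a place in the gene order, 5846 differed with vehicle, and 5747 after subtracting the median of the 50 neighbouring genes. Of these, 4956 were called both before and after, so broad copy number differences do not account for most of the breadth. The rest of the 5747 calls arose with the subtraction, so that count alone does not decide. A regional part was present, with r = 0.224 across genes between a gene and its neighbours against at most 0.03 over 100 shuffles. For FA in Cas9 control cells this r was 0.0248. Focal changes smaller than the window stay open. Other normalizations gave no fewer than 7397 features, so the choice among them does not account for the breadth. Each sets the arrays to a common distribution or median, so an error from that shared assumption was not tested. Of the probes detected on all 8 arrays 52.3% differed, against 19.2% of the others, so an excess of calls among dim probes was not seen. A difference between the lines other than the knockout could not be tested, since the labels give no further line.

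The counts over both treatments and over both genotypes were set against other splits of the arrays. Without an interaction in the model, the split by genotype called 9147 features and the highest other of 33 splits 0, so 1 of 33 reached the count. The split by treatment called 369 and the highest other of 33 splits 2, again 1 of 33. The experiments pair the arrays, and among the 17 splits that, like the real one, take the same number of arrays from each experiment, the highest other called 0 and 2. These 17 are too few for a share under 0.05. The other splits take unequal numbers from the experiments, and every split but the real one leaves the real difference in the residual spread, which lowers its count. Another 2 of 35 splits could not be fitted, because they follow the experiments or the other factor of the design.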
